A study of Mus musculus with 21 samples.

How the data were processed

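Total RNA from the left ventricle of mice carrying the αMHC-MerCreMer transgene and of wild-type mice was hybridised, 1 sample per array, to Affymetrix whole-transcript gene expression arrays. The file analysed here held 34760 probe sets on 21 arrays. The deposited values were log2 expression values made by RMA, per the submitters' processing notes, which name no version or software. RMA corrects the background of each probe, quantile normalises the arrays against each other and summarises the probes of a probe set on the log2 scale. Where arrays are quantile normalised together, a shift shared by most genes is removed. That all 21 arrays were processed together is inferred from their nearly equal medians, from 4.57 to 4.72, and a second quantile normalisation still changed the balance of higher and lower genes. The values were used as deposited with no further scaling. Array batches and scan dates are not given in the sources used here. The number of arrays limits the precision of each value.

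Probe sets were named through the platform's annotation table. It gave 1 gene for 21640 probe sets, several genes for 1321 and no entry for 11799. Only probe sets with 1 gene were used, and for each of the 19937 genes the probe set with the highest mean over all arrays was kept. In all, 99.6% of the Entrez identifiers matched the RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed updating. Gene lengths were taken from that table. Genes were tested if their log2 value reached 5 on at least 3 arrays, which left 11385 genes, 11380 of them with a length. The Cre and spike-in probe sets are not analysed here.

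Samples were grouped by genotype, injection and number of injection days as given in the labels, and sex was also taken from the labels. A linear model with 6 group means and sex as a covariate was fitted to all 21 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 14 residual and 3.97 prior degrees of freedom. Because most groups held 3 arrays, all groups shared 1 estimate of the spread. P values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Comparisons were 4 tamoxifen against 4 control injections in MerCreMer mice, 1 tamoxifen against 1 control injection in MerCreMer mice, 4 tamoxifen against 4 control injections in wild-type mice, and MerCreMer against wild-type mice after control injections. Further contrasts were the difference of the tamoxifen effects between the genotypes and between 4 and 1 injection days, MerCreMer mice after 4 against 1 control injections, and male against female mice. The labels describe separate replicates, but nothing says outright that each came from a separate animal. The p values therefore measure the spread between these samples, pooled over all groups, and not that of the groups compared alone.

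Gene lists for pathways, markers of cardiac and other cell types, and checks of sex and transgene were fixed, 42 in all. The designs, gene lists, alternatives and the rule for naming genes were chosen before the data were examined. Lists with several tested members were compared with all other genes by camera in limma with a preset correlation of 0.01 between genes, and the 204 tests of lists by comparison were adjusted together. In those tests 66 lists were called by camera, and 0 with a correlation estimated from the data, where the lowest adjusted p was 0.502. The rotation test fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes, kept 15 of the 66. A camera direction is relative to the other genes and can differ in sign from a list's own median. Members past the threshold were also counted with p values adjusted over the list alone.

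Named genes were, for each comparison, the 10 higher and 10 lower genes with the largest log2 change among those called whose groups did not overlap (no overlap condition for the interactions), up to 4 called members of each list with the smallest adjusted p or else the member with the smallest p, and a fixed panel. The fit was tested on simulated data with 100 genes changed by 0.5 and 100 by 1 log2 unit among 11385. With equal spread in all groups, the comparison of 4 tamoxifen with 4 control injections in MerCreMer mice recovered 53 and 97 of them and called 13 unchanged genes. In a second run the spread of the MerCreMer 4 tamoxifen arrays was widened by its measured ratio to the other groups. That run recovered 42 and 89 and called 307 unchanged genes. The spread so widened was the pooled one, which already holds this group, and so became wider than measured. These counts show the direction of the effect and not its size in the real comparison. For a simulated shift of -0.2 in oxidative phosphorylation, camera called that list and 0 of 33 others. The simulated genes varied independently of each other. This run therefore cannot show how list calls hold up where genes are correlated.

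Alternatives were no sex covariate, a block for replicate number, only the groups compared, array weights, trend and robust estimation, no filter or a stricter filter on dim probe sets (log2 value of 7), the mean of a gene's probe sets, every probe set on its own, a second quantile normalisation, centring of each array on its median, female arrays only, stricter thresholds (adjusted p under 0.01, or a log2 change of at least 1, which is 2-fold) and leaving out each array in turn. Chosen after seeing the data were a block for an array batch, the larger MerCreMer batch alone, and weights from each group's own residual variance. The batch was inferred from 1006 bright probe sets without an annotation entry that are numbered below the first gene probe set. Their score was centred within each MerCreMer group and split by its sign, so that every group falls into both batches by construction. Before centring, MerCreMer 4 tamoxifen replicate 2 lay at -0.3277, within the wild-type range of -1.296 to 2.396. The other arrays of the smaller batch lay at 3.398 to 3.994. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.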

Results

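Gene expression was measured in 21 left ventricle samples from mice aged 9 to 13 weeks. MerCreMer mice carry a transgene in which the α-myosin heavy chain promoter drives, in cardiomyocytes, a Cre recombinase fused to mutated oestrogen receptor ligand-binding domains. Tamoxifen, a ligand of the oestrogen receptor, moves this Cre into the nucleus. MerCreMer mice received tamoxifen (40 mg/kg per day) or control injections on 1 day or on 4 consecutive days, with 3 arrays per group. Wild-type mice received 4 tamoxifen injections (3 arrays) or 4 control injections (6 arrays). Ventricles were taken 4 days after the last injection. Each group of 3 held 1 male and 2 female mice, and the wild-type control group held 3 of each sex. Arrays of the MerCreMer 4 tamoxifen group correlated with each other at 0.9182 to 0.9742, below the lowest value in any other group, 0.9824. The residual variance of that group was 0.106, against 0.0153 to 0.0222 in the others. Unless another setting is named, SEs and p values rest on 1 spread shared by all groups. On average that spread is narrower than the MerCreMer 4 tamoxifen group's own and wider than those of the other groups. Comparisons without that group can therefore call too few genes. Control-injected MerCreMer and wild-type mice differed in 77 genes, and in 656 with weights from each group's own variance. In simulated data with the MerCreMer 4 tamoxifen spread made wider still than measured, 307 unchanged genes were called, against 13 with equal spread. These counts show the direction of the excess and not its size in the real comparison.

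The first comparison asked how 4 tamoxifen injections changed the ventricle of MerCreMer mice. Cacna1c, the pore-forming subunit of the cardiac L-type calcium channel, fell from 9.56 ± 0.08 to 7.32 ± 0.204 log2 units (SD, n = 3 in each group), a change of -2.24 with SE 0.0949 and limma adjusted p = 2.17e-11. Hmox1, the inducible haem oxygenase, rose from 6.05 ± 0.188 to 8.48 ± 0.0383 (change 2.43, SE 0.181, limma adjusted p = 1.06e-07, n = 3). Gpnmb, a glycoprotein of lipid-laden and phagocytic macrophages, rose by 2.45 (SE 0.169), and Tnnt1, the slow skeletal muscle troponin T, rose by 3.03 (SE 0.316). Gpnmb lay at 3.78 to 4.5 in the controls, below a log2 value of 5, so that its change is measured from near background. It reached 5 only on the 3 MerCreMer 4 tamoxifen arrays. Tnnt1 lay at 8.05, 9.98 and 10.45 after tamoxifen. Fgf13, a modulator of cardiac sodium channels, fell by 2.11 (SE 0.0882), Dmd, which encodes dystrophin, fell by 2.35 (SE 0.248), and Asb15, a muscle ubiquitin ligase subunit, fell by 2.62 (SE 0.266). Asb15 lay at 6.02, 6.07 and 4.49 after tamoxifen. Timp1, an inhibitor of matrix metalloproteinases, rose by 3.16 (SE 0.737, adjusted p = 0.00578), with array values of 6.45, 7.63 and 11.51 against 5.31 to 5.43 in the controls, and its change was 1.68 without MerCreMer 4 tamoxifen replicate 3. Angpt1, a ligand of the endothelial receptor Tie2, fell by 2.10 (SE 0.419), and Ccl12, a monocyte chemoattractant, rose by 2.47 (SE 0.338). The change of Ccl12 is also measured from near background, with controls at 4.36 to 4.73.

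**Figure D1:**
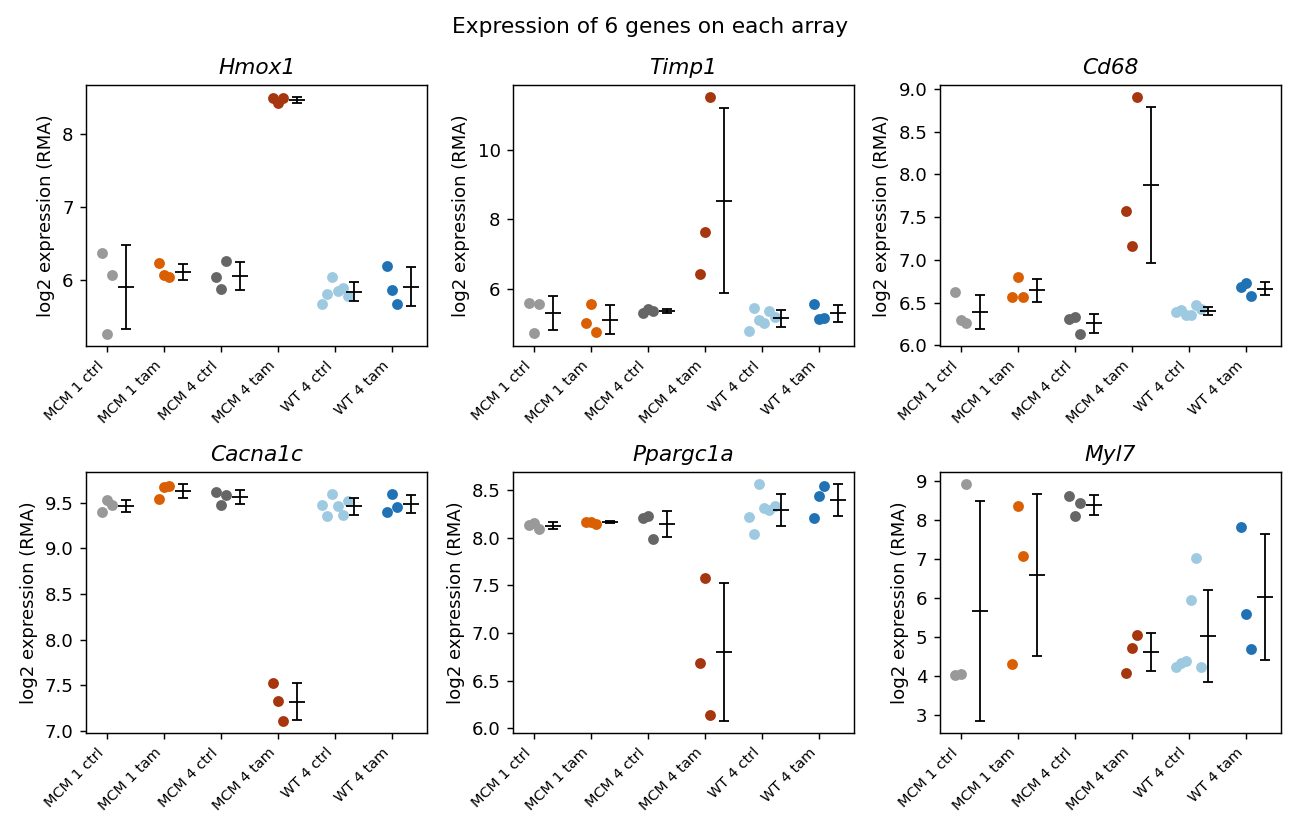
Log2 RMA expression of Hmox1, Timp1, Cd68, Cacna1c, Ppargc1a and Myl7 in each array (points) with group mean and SD (bars), for MerCreMer (MCM) and wild-type (WT) mice after 1 or 4 control (ctrl) or tamoxifen (tam) injections. Hmox1 lies at 8.43 to 8.5 in the MerCreMer 4 tamoxifen arrays and at 5.87 to 6.25 in their controls, while Timp1 spans 6.45 to 11.51 within that group.

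Of 11385 genes, limma called 2653, with 1582 higher and 1071 lower after tamoxifen, and 149 higher and 132 lower by at least 2-fold. The excess of higher genes was not stable, with 1368 higher and 1313 lower after a second quantile normalisation and 710 higher and 792 lower with female arrays only. Of these 2653, 2269 had groups that did not overlap, and 27.9% of all genes did not overlap, where chance gives 10%. The number called varied with the setting, being 18 (5 higher, 13 lower) with only the 6 arrays compared, 903 with each group's own variance as weights, 1489 with array weights, 1502 with female arrays only and 1654 with the replicate block. It was 1713 without MerCreMer 4 control replicate 1, 1648 without MerCreMer 4 control replicate 3, 2707 with the inferred array batch as a block and 654 within the larger inferred MerCreMer batch. The smaller inferred batch held 1 array per group, too few for a test. Cacna1c, Camk2d, Fgf13, Gpnmb, Hmox1, Kcnv2 and Myl7 were the named genes still called with only the arrays compared, 7 of 120.

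Calcium handling and ion channel genes fell as a group. Of 33 tested, 18 fell, 1 rose and 14 were not called (18 and 1 adjusted over the list alone), with a median change of -0.55 and adjusted p = 6.09e-10 by camera, and adjusted p = 0.502 with an estimated correlation. Camk2d, a calcium/calmodulin-dependent kinase, fell by 1.21 (SE 0.0724), Slc8a1, the sodium-calcium exchanger, fell by 1.38 (SE 0.179), and Kcnv2, a potassium channel subunit, fell by 1.37 (SE 0.16). Ryr2, the calcium release channel of the sarcoplasmic reticulum, fell by 1.34 (SE 0.202). Pln, the inhibitor of the calcium pump, fell by 0.77 (SE 0.15) and by 0.48 without MerCreMer 4 tamoxifen replicate 3. Atp2a2, the pump itself, was at -0.11 (SE 0.0592, adjusted p = 0.192). Of 29 sarcomere genes 10 fell, 1 rose and 18 were not called (11 and 1 adjusted over the list alone), with a median of -0.11 and adjusted p = 0.00368, and adjusted p = 0.714 with an estimated correlation. Nexn and Nebl, actin-binding proteins of the Z-disc, fell by 0.79 (SE 0.118) and 1.07 (SE 0.174). The sarcomere list was no longer called without MerCreMer 4 tamoxifen replicate 1 (median -0.07) and its median was -0.19 without replicate 2 and -0.06 without replicate 3 of that group. Myh6 and Myh7, the cardiac myosin heavy chains, were at -0.09 (adjusted p = 0.401) and 0.22 (adjusted p = 0.698).

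Among 16 cardiomyocyte markers 2 fell, Ryr2 and Pln, and 14 were not called (0 rose). Their median was -0.165 (adjusted p = 0.00901, and adjusted p = 0.714 with an estimated correlation), and it was -0.255 without MerCreMer 4 tamoxifen replicate 1 and -0.05, no longer called, without replicate 3. Myl7, the atrial myosin light chain, fell by 3.77 (SE 1.11, adjusted p = 0.0211), and was not called without MerCreMer 4 control replicate 1 (change -3.28). Its values were 8.11 to 8.6 in the MerCreMer 4 controls and 4.07 to 5.04 after tamoxifen, but also ranged from 4.03 to 8.93 among MerCreMer 1 controls and from 4.22 to 7.02 among wild-type controls. As Myl7 is an atrial transcript, its level also measures atrial tissue in a ventricular sample. Of the 10 atrial and conduction markers Myl7 alone was called, and their median was -0.17, and 0.028 without MerCreMer 4 tamoxifen replicate 3.

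Fuel oxidation genes fell as groups, by camera with the preset correlation. Of 37 genes of fatty acid oxidation and PPARA targets 18 fell, 1 rose and 18 were not called (30 and 1 adjusted over the list alone), with a median of -0.51 and adjusted p = 3.23e-09, and adjusted p = 0.714 with an estimated correlation. Ppargc1a, a coactivator of mitochondrial biogenesis, fell by 1.34 (SE 0.223), Esrrg, an orphan nuclear receptor of oxidative metabolism, fell by 1.00 (SE 0.109), and Lpl, lipoprotein lipase, fell by 0.51 (SE 0.104). Of 74 oxidative phosphorylation genes 19 fell and 55 were not called (22 fell adjusted over the list alone), with a median of -0.245 and adjusted p = 4.71e-11, and adjusted p = 0.714 with an estimated correlation. Uqcr10, a subunit of complex III, fell by 0.59 (SE 0.131), and by 0.36 without MerCreMer 4 tamoxifen replicate 3. In the tricarboxylic acid cycle 5 of 20 genes fell (12 adjusted over the list alone), with a median of -0.28 and adjusted p = 1.45e-05, and adjusted p = 0.714 with an estimated correlation. Mdh1, malate dehydrogenase, fell by 0.47 (SE 0.116), and by 0.24 without replicate 3. These shifts were uneven between arrays, with oxidative phosphorylation medians of -0.01, -0.07 and -0.61 on MerCreMer 4 tamoxifen replicates 1, 2 and 3 relative to the MerCreMer controls, and fatty acid oxidation medians of -0.05, -0.33 and -1.27 (macrophage markers on the same arrays, 0.88, 0.30 and 1.90). Without replicate 3 the medians were -0.21 for fatty acid oxidation, -0.06 for oxidative phosphorylation and -0.08 for the tricarboxylic acid cycle, all still called. That of the tricarboxylic acid cycle was -0.435 without replicate 1. Of 21 glycolysis genes 5 rose and 5 fell (median 0.01, mean -0.03, adjusted p = 0.712; 6 and 5 adjusted over the list alone). Pdk4, the pyruvate dehydrogenase kinase, was at -0.38 (adjusted p = 0.588).

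Macrophage and monocyte markers rose. Of 21 tested 19 rose and 2 were not called (20 rose adjusted over the list alone), with a median of 1.02 and adjusted p = 6.09e-10, and adjusted p = 0.714 with an estimated correlation. Cd68, a lysosomal protein of macrophages, rose by 1.62 (SE 0.265), Mrc1, the mannose receptor, by 1.22 (SE 0.199), and the complement genes C1qb and C1qc by 1.02 (SE 0.172) and 1.06 (SE 0.176). The median was 0.56, still called, without MerCreMer 4 tamoxifen replicate 3. Of 29 chemokine, cytokine and acute phase genes 13 rose and 16 were not called (18 rose adjusted over the list alone), with a median of 0.41 and adjusted p = 1.6e-05, and adjusted p = 0.714 with an estimated correlation; without replicate 3 the median was 0.21. Ccl6, a chemokine, rose by 1.42 (SE 0.249), and Stat3, a transcription factor of cytokine signalling, by 0.82 (SE 0.105). Of 34 interferon response genes 9 rose and 25 were not called (9 rose adjusted over the list alone), with a median of 0.26 and adjusted p = 0.00421, and adjusted p = 0.714 with an estimated correlation. Ifi27l2a rose by 1.03 (SE 0.17) and Irf9, a subunit of the interferon-activated factor ISGF3, by 0.69 (SE 0.131). The interferon list was no longer called without MerCreMer 4 tamoxifen replicate 1 (median 0.2), and its median was 0.40 without replicate 2. Lcn2, the only neutrophil marker tested and also an acute phase gene, rose by 2.40 (SE 0.504), from controls near background at 4.69 to 4.79 to 8.22, 5.02 and 8.18. Thy1, Kit and Ager, the only tested markers of T cells, mast cells and lung, were at 0.13 (adjusted p = 0.489), -0.28 (adjusted p = 0.136) and -0.09 (adjusted p = 0.676), and 0 B cell markers were bright enough for the limma test. Thy1 is also on the fibroblast list, so that its value does not measure T cells alone.

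Genes of oxidative stress and metallothionein rose as a group. Of 35 tested 14 rose and 21 were not called (14 rose and 2 fell adjusted over the list alone), with a median of 0.24 and adjusted p = 0.00057, and adjusted p = 0.502 with an estimated correlation. Besides Hmox1, Txnrd1, a thioredoxin reductase, rose by 0.89 (SE 0.113), Srxn1, sulfiredoxin, by 0.90 (SE 0.14), and Gpx3, a secreted glutathione peroxidase, by 0.85 (SE 0.12). The list medians on MerCreMer 4 tamoxifen replicates 1, 2 and 3 were 0.25, 0.30 and 0.37 (macrophage markers on the same arrays, 0.88, 0.30 and 1.90). Of 28 cytosolic chaperones 9 rose, 1 fell and 18 were not called (11 and 1 adjusted over the list alone), with a median of 0.22 and adjusted p = 0.0281, and adjusted p = 0.714 with an estimated correlation. Hsp90aa1 and Hspa1a, heat-inducible chaperones, rose by 0.95 (SE 0.168) and 0.66 (SE 0.136), but the list was not called without replicate 3 (median 0.15). Of 32 cholesterol biosynthesis and SREBP target genes 9 rose and 1 fell (10 and 2 adjusted over the list alone), with a median of 0.23 and adjusted p = 0.0281, and adjusted p = 0.672 with an estimated correlation. Scd2, a fatty acid desaturase, rose by 1.64 (SE 0.19); the cholesterol list was not called without replicate 3 (median 0.115) and its median was 0.37 without replicate 2.

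Of 47 extracellular matrix and fibrosis genes 15 rose, 2 fell and 30 were not called (20 and 2 adjusted over the list alone), with a median of 0.53 and adjusted p = 0.00051, and adjusted p = 0.723 with an estimated correlation. Pcolce, which enhances procollagen processing, rose by 0.70 (SE 0.15), while Col1a1 and Col3a1, the main fibrillar collagens, were at 0.90 (adjusted p = 0.0676) and 0.89 (adjusted p = 0.0675). The matrix median was 0.12 and no longer called without MerCreMer 4 tamoxifen replicate 3, and its medians by array were 0.23, 0.06 and 1.22. Of 24 cardiac stress and foetal genes 10 rose, 1 fell and 13 were not called (12 and 1 adjusted over the list alone), with a median of 0.32 and adjusted p = 0.00175, and adjusted p = 0.714 with an estimated correlation. Xirp1, an actin-binding protein of the intercalated disc, rose by 0.79 (SE 0.11), Tnfrsf12a, the TWEAK receptor, by 1.47 (SE 0.244), and Acta1, skeletal α-actin, by 1.39 (SE 0.322). The stress list was not called without replicate 3 (median 0.24), and its median was 0.71 without replicate 1 and 0.56 without replicate 2. Nppb, brain natriuretic peptide, rose by 1.73 (SE 0.505, adjusted p = 0.0204), a call lost without MerCreMer 4 control replicate 3 (1.47) and without MerCreMer 4 tamoxifen replicate 3 (1.13), and Nppa, atrial natriuretic peptide, was at 1.02 (adjusted p = 0.0831). Immediate early genes gave 9 higher and 1 lower of 23, also adjusted over the list alone (median 0.31, adjusted p = 0.00427, and adjusted p = 0.714 with an estimated correlation), among them Atf3, a stress transcription factor, which rose by 1.73 (SE 0.234), and Nr4a1, a nuclear receptor, by 1.53 (SE 0.331). That list was not called without MerCreMer 4 tamoxifen replicate 3 (median 0.06), and its median was 0.515 without replicate 1. Of 14 cell cycle genes 6 rose and 1, Cenpa, fell (7 and 1 adjusted over the list alone; median 0.46, adjusted p = 0.00901, and adjusted p = 0.714 with an estimated correlation), and the list was not called without replicate 3 (median 0.16). With the stricter filter its median was 0.009, with no call and the camera direction reversed. That filter also ended the calls of the chemokine (0.331), interferon (0.092), chaperone (0.171), cholesterol (0.214) and immediate early (0.321) lists. Array weights ended those of the cell cycle (0.129), matrix (0.123), interferon (0.091), cholesterol (0.08), sarcomere (-0.012) and cardiomyocyte (-0.04) lists, and female arrays alone that of the sarcomere list (-0.095). Macrophage markers, as medians on the same arrays, were at 0.88, 0.30 and 1.90.

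Among the marker lists of the remaining cell types only the endothelial one was called, in the lower direction. Of 16 endothelial markers 4 fell and 12 were not called, with a median of -0.25 and adjusted p = 0.00421, and adjusted p = 0.714 with an estimated correlation; the median was -0.39 without MerCreMer 4 tamoxifen replicate 1 and -0.1 without replicate 3. Erg, an endothelial transcription factor, fell by 0.31 (SE 0.08). Lists that were not called included the fibroblast markers (14 tested, median 0.14, adjusted p = 0.513), smooth muscle and pericyte markers (12 tested, median 0.00, adjusted p = 0.989), and mesothelial and valve markers (7 tested, median 0.29, adjusted p = 0.0671). In the last of these Krt18, a keratin, rose by 1.98 (SE 0.248). Skeletal muscle markers (6 tested, median 0.155, adjusted p = 0.312) held a called member in Tnnt3, the fast skeletal troponin T, which rose by 1.84 (SE 0.249). Medians were 0.06 for 4 erythroid, -0.175 for 6 adipocyte and 0.00 for 3 Schwann cell and neuron markers, none of these lists being called by limma's camera.

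Lists of genome damage, cell death and protein stress were not called by camera. Of 31 p53 targets and DNA damage response genes 8 rose and 4 fell (median 0.08, adjusted p = 0.383), with Mdm2, the ubiquitin ligase of p53, rising by 0.34 (SE 0.0721) and Perp, a p53-induced membrane protein, falling by 0.69 (SE 0.104) on the log2 scale. Of 28 DNA repair genes 0 rose and 1 fell at limma's threshold (median 0.04, adjusted p = 0.808), and of 29 apoptosis and necroptosis genes 4 rose and 1 fell (median 0.10, adjusted p = 0.46). The unfolded protein and integrated stress response gave 6 higher and 3 lower of 40 (median 0.23, adjusted p = 0.0775, and a median of 0.059 without MerCreMer 4 tamoxifen replicate 3), and ubiquitin ligase and autophagy genes gave 10 higher and 3 lower of 31 (median 0.15, adjusted p = 0.169), including Psmd1, a proteasome subunit, which rose by 0.39 (SE 0.0577). Hormone and clock lists were not called either. Oestrogen response genes gave 5 higher and 5 lower of 23 (median 0.06, camera direction lower, adjusted p = 0.565), with Fhl2, a cardiac LIM protein, which fell by 0.96 (SE 0.0839). Glucocorticoid response genes gave 4 higher and 7 lower of 28 (median -0.24, mean 0.02, adjusted p = 0.207), with Klf15, a regulator of cardiac metabolism, which fell by 1.07 (SE 0.181). Circadian clock genes gave 1 higher and 4 lower of 18 (median -0.16, adjusted p = 0.212). Adjusted over the list alone, limma's counts of higher and lower genes were unchanged for the p53, unfolded protein, oestrogen and glucocorticoid lists, and were 0 and 0 for DNA repair, 3 and 1 for apoptosis, 11 and 5 for ubiquitin ligases and autophagy, and 1 and 5 for the clock.

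**Figure D2:**
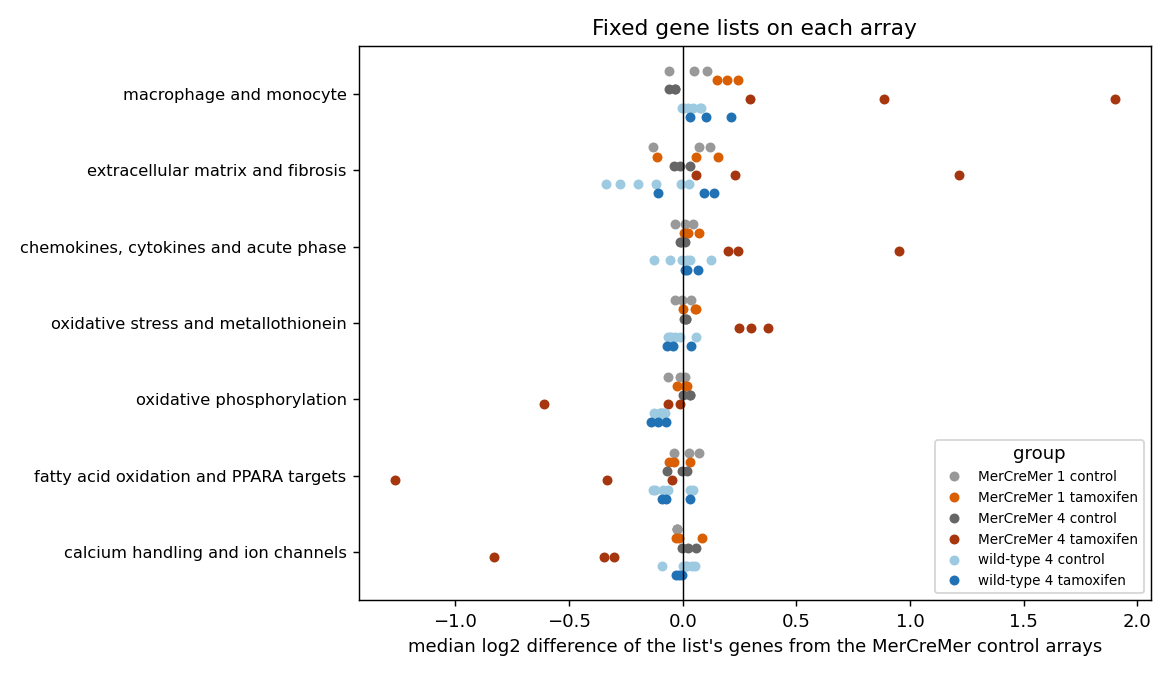
Median log2 difference of 7 gene lists from the MerCreMer control (ctrl) arrays, 1 point per array, by group of MerCreMer (MCM) and wild-type (WT) mice given 1 or 4 control or tamoxifen (tam) injections. In the MerCreMer 4 tamoxifen group the macrophage list lies at 0.30 to 1.90, the oxidative phosphorylation list at -0.61 to -0.01 and the calcium handling list at -0.83 to -0.30.

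A single tamoxifen injection was compared with a single control injection in MerCreMer mice. Ptprn2, a protein of dense-core vesicles, rose by 1.18 (SE 0.164, limma adjusted p = 0.0132), with values of 5.85 to 5.97 against 4.63 to 4.93 in the controls, which lie near background. The interferon response genes rose as a list, with a median of 0.24 and positive changes in 32 of 34 (adjusted p = 3.97e-13 by camera, and adjusted p = 0.502 with an estimated correlation). None of the 34 was called over all genes by limma, and 3 were called adjusted over the list alone. Ifih1, a sensor of viral RNA, had the smallest p of the list, with a change of 0.36 (SE 0.0952, adjusted p = 1). The list medians of the 3 treated arrays above the MerCreMer controls were 0.12, 0.26 and 0.36. Ftl1, the ferritin light chain, was at 1.08 (SE 0.212, adjusted p = 0.296), and Cacna1c was at 0.16 (SE 0.0949, adjusted p = 1).

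Ptprn2 was the 1 gene called of 11385, 380 genes had an unadjusted p under 0.05, and 10.4% of all genes had groups that did not overlap, where chance gives 10%. Ptprn2 was called when MerCreMer 1 control replicate 2 was left out and was not called without any 1 of the other 5 arrays, where its adjusted p ranged from 0.0683 to 0.25. Other lists were called with smaller shifts. Erythroid markers had a median of 0.206 (4 of 4 positive, adjusted p = 0.0323, and adjusted p = 0.714 with an estimated correlation). They were not called without MerCreMer 1 control replicates 1 (0.126) and 3 (0.23) or MerCreMer 1 tamoxifen replicate 2 (0.048), and 0.388 without MerCreMer 1 tamoxifen replicate 3. Within the larger MerCreMer batch their direction turned, with a median of -0.232 and no call. Skeletal muscle markers had a median of -0.102 (adjusted p = 0.0323, and adjusted p = 0.502 with an estimated correlation). They were not called without MerCreMer 1 control replicate 2 (-0.109) or MerCreMer 1 tamoxifen replicates 1 (-0.039) and 3 (-0.045), and -0.178 and -0.235 without MerCreMer 1 control replicate 1 and MerCreMer 1 tamoxifen replicate 2. Smooth muscle and pericyte markers had a median of -0.071 (adjusted p = 0.0373, and adjusted p = 0.559 with an estimated correlation). They were not called without MerCreMer 1 control replicates 1 (-0.091) and 2 (-0.034) or MerCreMer 1 tamoxifen replicates 1 (-0.09) and 2 (-0.051). Macrophage markers had a median of 0.18 (20 of 21 positive, adjusted p = 0.0323, and adjusted p = 0.818 with an estimated correlation), with 0.09 and no call without MerCreMer 1 control replicate 2, and no call without MerCreMer 1 control replicate 3 (0.17) or MerCreMer 1 tamoxifen replicate 1 (0.14). The calls of immediate early genes (-0.08, adjusted p = 0.00368, and 0.714 as the adjusted p with an estimated correlation), cytosolic chaperones (-0.06, adjusted p = 0.00744, and adjusted p = 0.714 with an estimated correlation) and fatty acid oxidation (-0.04, adjusted p = 0.0494, and adjusted p = 0.84 with an estimated correlation) were also lost when single arrays were left out. Immediate early genes were at -0.04 without MerCreMer 1 control replicate 2, -0.18 without control replicate 1 and -0.13 without control replicate 3. Within the larger MerCreMer batch they were at 0.039 and not called. Chaperones were at -0.02 without control replicate 1, and at 0.013 and not called within that batch. Fatty acid oxidation genes were at -0.10 without control replicate 1, 0.01 without control replicate 3, -0.04 without MerCreMer 1 tamoxifen replicate 1 and -0.05 without MerCreMer 1 tamoxifen replicate 3. Of 23 settings, with fry and the estimated correlation among them, limma called the interferon list in 21, immediate early genes in 18, chaperones in 17, macrophage and erythroid markers in 15, skeletal muscle markers in 13, fatty acid oxidation in 11 and smooth muscle markers in 10. Over the genes called after 4 injections, the changes after 1 and 4 injections had the same sign in 53.8%, with a correlation across genes of 0.0758 (Spearman 0.0786), genes not being independent replicates.

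Wild-type mice given 4 tamoxifen injections were compared with wild-type controls to show what tamoxifen does without Cre. Changes of fibroblast markers were positive in all 14 tested genes, none of them called singly by limma, with a median of 0.25 and adjusted p = 1.23e-05 by camera, and adjusted p = 0.502 with an estimated correlation. Matrix genes rose as a list, with a median of 0.19 and positive changes in 42 of 47 (adjusted p = 6.37e-05, and adjusted p = 0.714 with an estimated correlation), but were not called without wild-type 4 tamoxifen replicate 1 (0.10). Erythroid markers had a median of 0.44 over 4 genes (adjusted p = 7.27e-05, and adjusted p = 0.502 with an estimated correlation), 3 of them called adjusted over the list alone. Interferon response genes had a median of 0.16 with 30 of 34 positive (adjusted p = 6.11e-06, and adjusted p = 0.714 with an estimated correlation), which was 0.04 and not called without wild-type 4 tamoxifen replicate 2, and 0.255 without replicate 1. Apoptosis and necroptosis genes had a median of 0.075 with 22 of 29 positive (adjusted p = 0.0069, and adjusted p = 0.502 with an estimated correlation). Cell cycle genes had a median of 0.099 with 14 of 14 positive (adjusted p = 0.0207, and adjusted p = 0.714 with an estimated correlation). Lists called in the lower direction were cytosolic chaperones (median -0.067, adjusted p = 0.00402, and adjusted p = 0.672 with an estimated correlation), immediate early genes (-0.072, adjusted p = 0.0282, and adjusted p = 0.714 with an estimated correlation) and sarcomere genes (-0.037, adjusted p = 0.0281, and adjusted p = 0.714 with an estimated correlation). The chaperone list was at -0.036 and not called without wild-type 4 control replicate 3, and at -0.03 without wild-type 4 tamoxifen replicate 3. The sarcomere list was not called without wild-type 4 control replicates 2 (-0.038) and 3 (-0.042) or wild-type 4 tamoxifen replicate 3 (-0.035). The immediate early list was not called without wild-type 4 control replicates 1 (-0.111), 2 (-0.086) and 3 (-0.091) or wild-type 4 tamoxifen replicates 2 (-0.042) and 3 (-0.077). It was at -0.111 without wild-type 4 control replicate 4 and -0.171 without wild-type 4 tamoxifen replicate 1. The cell cycle list was not called without wild-type 4 control replicate 3 (0.092) or wild-type 4 tamoxifen replicate 1 (0.081). Of 25 settings, with fry and the estimated correlation among them, limma called the fibroblast list in 23, matrix and erythroid lists in 22, chaperone, interferon and apoptosis lists in 21, cell cycle in 18, sarcomere in 14 and immediate early genes in 12. Esr1, which encodes oestrogen receptor α, was at 0.76 (SE 0.143, adjusted p = 0.179), and Myh7, the slow myosin heavy chain, at -0.84 (SE 0.313, adjusted p = 1).

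No gene was called here by limma (0 of 11385), and 294 had an unadjusted p under 0.05. In 3.42% of genes the groups did not overlap, where chance gives 2.38%. Simulated changes of 0.5 and 1 log2 unit were recovered in 68 and 96 of 100 genes in this comparison. There many genes were changed at once, which eases the adjusted threshold. Where few genes change, fewer would be recovered, so that changes of these sizes could be missed. The largest change in the real data, of 1.29 log2 units in size, was not called. Hmox1 and Cacna1c had group means of 5.90 ± 0.267 (SD, n = 3) and 9.48 ± 0.0979 after tamoxifen, against 5.84 ± 0.127 and 9.46 ± 0.0909 (SD, n = 6). Over the 2653 genes called in MerCreMer mice, changes had the same sign in 56.4%, with a correlation across genes of 0.111 (Spearman 0.131).

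The tamoxifen effects of the genotypes were compared by their interaction, the effect of 4 injections in MerCreMer mice minus that in wild-type mice. Cacna1c was lower by this measure at -2.26 (SE 0.126, adjusted p = 3.54e-09), and Fgf13 at -2.04 (SE 0.117), while Gpnmb at 2.38 (SE 0.224), Hmox1 at 2.33 (SE 0.24) and Hspa1l, a heat shock protein, at 2.06 (SE 0.271) were higher. Of 33 calcium handling genes 15 were lower and 1 higher (17 and 1 adjusted over the list alone), with a median of -0.59 and adjusted p = 5.7e-10, and adjusted p = 0.502 with an estimated correlation. Macrophage markers had a median of 0.94 with 7 of 21 higher (18 adjusted over the list alone; adjusted p = 1.66e-08, and adjusted p = 0.714 with an estimated correlation), which was 0.45 without MerCreMer 4 tamoxifen replicate 3. Oxidative stress genes had a median of 0.25 with 9 of 35 higher (12 adjusted over the list alone; adjusted p = 0.000518, and adjusted p = 0.502 with an estimated correlation). Oxidative phosphorylation had a median of -0.23 with 1 of 74 lower (0 adjusted over the list alone; adjusted p = 6.09e-10 by camera in limma, and adjusted p = 0.714 with an estimated correlation), which was -0.04 without replicate 3. Fatty acid oxidation had a median of -0.57 with 4 of 37 lower, also adjusted over the list alone (adjusted p = 1.05e-09, and adjusted p = 0.714 with an estimated correlation), which was -0.23 without replicate 3.

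In all, 908 genes differed in tamoxifen effect between the genotypes, 507 higher and 401 lower (474 and 514 after a second quantile normalisation, 88 and 104 with female arrays only), and 884 of them were called in the same direction in MerCreMer mice, whose arrays enter both comparisons. The count was 528 with only the groups compared, 516 with group variance weights, 192 with female arrays only, 27 (8 higher, 19 lower) with the replicate block, 501 and 543 without MerCreMer 4 control replicates 1 and 3, 1714 and 2242 without MerCreMer 4 tamoxifen replicates 1 and 2, and 556, 582 and 510 without wild-type 4 tamoxifen replicates 1, 2 and 3. The replicate block takes the 3 female wild-type controls out of the comparison, as their replicate numbers occur in no other group.

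The effect of 4 injections was also compared with that of 1 injection in MerCreMer mice. Fhod3, a formin of the cardiac sarcomere, differed by -2.05 (SE 0.0903, adjusted p = 1.23e-10), and Cacna1c by -2.40 (SE 0.134, adjusted p = 3.84e-09). Fhod3 lay at 7.36 to 7.47 on the MerCreMer 4 tamoxifen arrays. Higher by this measure were Gpnmb at 2.27 (SE 0.239), Hmox1 at 2.22 (SE 0.256) and Atf3 at 1.91 (SE 0.331). Of 33 calcium handling genes 14 were lower and 1 higher (18 and 1 adjusted over the list alone), with a median of -0.73 and adjusted p = 1.05e-10, and adjusted p = 0.502 with an estimated correlation; the median was -0.43 without MerCreMer 4 tamoxifen replicate 3. Macrophage markers had a median of 0.83 with 4 of 21 higher (12 adjusted over the list alone; adjusted p = 1.35e-07, and adjusted p = 0.714 with an estimated correlation), which was 0.46 without replicate 3 and 1.25 without replicate 2. Oxidative stress genes had a median of 0.235 with 5 of 35 higher (8 adjusted over the list alone; adjusted p = 0.00505, and adjusted p = 0.559 with an estimated correlation).

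In all, 658 genes differed between the effects of 4 and 1 injections, 316 higher and 342 lower. Of these, 644 were called in the same direction after 4 injections, a comparison whose arrays enter both. The count was 113 with only the groups compared, 408 with group variance weights, 425 with each array centred, 139 with female arrays only, 232 with the replicate block, 411 with no filter, 697 with the array batch as a block and 4 within the larger MerCreMer batch. It was 377 without MerCreMer 1 control replicate 1, 396, 409 and 390 without MerCreMer 1 tamoxifen replicates 1, 2 and 3, 409 and 383 without MerCreMer 4 control replicates 1 and 3, and 1374 and 1955 without MerCreMer 4 tamoxifen replicates 1 and 2. Between 4 and 1 control injections in MerCreMer mice limma called 0 genes (375 with an unadjusted p under 0.05).

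Control-injected MerCreMer and wild-type mice were compared to show what the transgene and the strain do without tamoxifen. Esr1 was higher in MerCreMer mice by 1.79 (SE 0.143, limma adjusted p = 2.98e-06), lying at 7.2 to 7.75 on MerCreMer arrays, tamoxifen-treated ones included, and at 5.47 to 6.08 in wild-type controls. The transgene itself carries mutated oestrogen receptor sequence. The small RNA genes n-R5s136, a ribosomal RNA gene copy, and Snord49b, a small nucleolar RNA, were higher by 1.53 (SE 0.146) and 0.86 (SE 0.101). Oxidative phosphorylation genes were higher as a list, with 5 of 74 called (12 adjusted over the list alone), 64 of 74 positive and a median of 0.12 (adjusted p = 4.73e-07, and adjusted p = 0.723 with an estimated correlation). The atrial transcript Myl7 lay at 8.11 to 8.6 in these MerCreMer controls and at 4.22 to 7.02 in the wild-type controls. Whether a difference in tissue content bears on the list's shift was not tested. Apoptosis and necroptosis genes had a median of 0.10 (adjusted p = 0.0281, and adjusted p = 0.502 with an estimated correlation), with 0.05 and no call without MerCreMer 4 control replicate 1, and medians of 0.05 and 0.06 without wild-type 4 control replicates 3 and 5. Endothelial markers had a median of 0.084 with 1 of 16 called (3 adjusted over the list alone; adjusted p = 0.0461, and adjusted p = 0.714 with an estimated correlation). They were not called without MerCreMer 4 control replicates 1 (0.128) and 2 (0.058) or wild-type 4 control replicates 1 (0.079), 2 (0.058), 4 (0.079) and 6 (0.084). Their median was 0.146 without MerCreMer 4 control replicate 3. Sarcomere genes were called lower as a list, with a median of -0.05 (adjusted p = 0.0292, and adjusted p = 0.714 with an estimated correlation). They were not called without MerCreMer 4 control replicate 1 (-0.018) or wild-type 4 control replicates 2 (-0.047) and 3 (-0.051). With each array centred on its median they were at 0.023, also not called. Of 25 settings, with fry and the estimated correlation among them, limma called oxidative phosphorylation in 23, apoptosis in 20, sarcomere in 14 and endothelial markers in 12.

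Of 11385 genes 77 were called, 62 higher and 15 lower in MerCreMer mice, and 186 higher and 10 lower with each array centred on its median. Of the 77, 76 had groups that did not overlap, and 12.5% of all genes did not overlap, where chance gives 2.38%. The count was 12, 10 and 39 without MerCreMer 4 control replicates 1, 2 and 3, 46, 128, 38 and 40 without wild-type 4 control replicates 2, 3, 5 and 6, 280 with only the groups compared, 656 with group variance weights, 1069 with array weights, 260 with a block for the smaller MerCreMer batch, 12 with female arrays only and 1, Esr1, with the replicate block, which takes the 3 female wild-type controls out of the comparison. Esr1, n-R5s136 and Snord49b were called in each of these leave-one-out fits.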

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

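The test of a difference between array batches was chosen after the result was seen. The effect of 4 tamoxifen injections differed between MerCreMer and wild-type mice in 908 genes by the interaction term, and 13 of 100 splits of the same arrays called as many genes, the highest other split calling 1987. All 13 are among the 15 splits that kept the 3 MerCreMer 4 tamoxifen arrays together, and splits that parted these arrays called at most 3 genes, so that the counts follow the structure of the samples and chance is not excluded by this count. The effect differed between 4 and 1 injections in 658 genes, and 8 of 100 splits called as many, the highest other split calling 940 and the highest split that parted the 3 arrays calling 7. Chance is not excluded by that count either.

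Among 241 named genes, 18 had 1 wild-type 4 control array far from the other 5, as the gap to the nearest array over the whole range, where about 12 would be found by chance. On replicate 3 these were Dbp (0.88), Nr1d1 (0.853), Bhlhe41 (0.741), Nfil3 (0.652), Mt1 (0.703), Mt2 (0.661), Zbtb16 (0.658), Jun (0.635), Gclm (0.694), Acaca (0.69), Olfr1148 (0.798) and Snord15a (0.786). The first 4 are genes of the circadian clock, and Mt1, Mt2 and Zbtb16 are known targets of glucocorticoids. On replicate 2 they were Angptl4 (0.729), Cd1d2 (0.654) and Nexn (0.69), on replicate 1 Gbp3 (0.683) and Pgk1 (0.725), and on replicate 6 Thy1 (0.707).

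Probe sets without an annotation entry also carried signal. Of 3777 bright enough to test, limma called 93 after 4 tamoxifen injections in MerCreMer mice (54 higher, 39 lower) and 97 between control-injected MerCreMer and wild-type mice (61 higher, 36 lower).

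Small RNA genes were called often between the control-injected genotypes, at 13 of 99 tested (13.1%), 12 of them higher in MerCreMer mice, although the median change over all 99 was -0.096, against 64 of the other genes (Fisher's exact test, p = 8.4e-14). That test treats genes on the same arrays as independent, which they are not, so that its p value overstates the evidence. The batch difference of these 13 genes between the 2 inferred MerCreMer array batches was 0.079 of their genotype difference (medians -0.07 and 0.87). This cannot decide whether those batches are the source. The 13 were chosen by a fit without the batch, which calls genes with a large batch difference less readily. A difference between the arrays of the genotypes stays open, since 19 of 2137 low-numbered probe sets without an entry, 0.889%, also differed between the genotypes, against 0.676% of genes. A biological difference between the strains stays open as well, and was not tested.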

How the results depend on the processing

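The array batch block, the larger MerCreMer batch alone and the group variance weights were chosen after seeing the data. The array batches are inferred from the values and are not given in the labels. Counts are called in the order 4 injections in MerCreMer mice (2653), 1 injection (1), wild-type (0), genotype (77), tamoxifen effect by genotype (908), by injection days (658) and sex (33), and are given where they moved by over 1.5 times. The comparison of 4 with 1 control injections gave 0 in limma in the main setting (375 with an unadjusted p under 0.05), 1 gene with no filter on dim probe sets, and 0 in every other setting run. Counts stayed within 1.5 times without the sex covariate (the sex count cannot be had there), and all of them with the mean of probe sets, with trend and robust estimation and after a second quantile normalisation (2681 for 4 injections).

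With only the groups compared, which leaves each test its own spread, the counts were 18, 2, 2, 280, 528 and 113 for the first 6. Array weights gave 1489 for 4 injections, 2 for 1 injection, 2 for wild-type, 1069 for genotype and 95 for sex. Group variance weights gave 903 for 4 injections, 3 for wild-type, 656 for genotype, 516 and 408 for the interactions and 59 for sex. Female arrays, being fewer, gave 1502, 2, 2, 12, 192 and 139 for the first 6. Centring each array gave 196 for genotype and 425 for injection days. Without a filter 1 injection gave 2 and injection days 411; the stricter filter gave 0 for 1 injection and 19 for sex. Every probe set gave 235 for genotype. An adjusted p under 0.01 gave 1147, 0, 16, 296, 214 and 17 (all but wild-type), and a log2 change of at least 1 gave 281, 5, 209, 177 and 7 (all but 1 injection and wild-type). The array batch block gave 260 for genotype, and the larger MerCreMer batch, with 2 arrays a group, 654 for 4 injections and 4 for injection days. The smaller batch has 1 array per group, too few for a test. Where the smaller number of arrays or the stricter threshold does not account for a change, the cause was not tested. Leaving out single arrays gave 1648 to 3846 for 4 injections, 0 to 1 for 1 injection, 0 to 0 for wild-type, 10 to 128 for genotype, 501 to 2242 and 377 to 1955 for the interactions, 0 to 0 for control injections and 21 to 70 for sex.

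The replicate numbers do not pair the samples. Correlations of same-numbered deviations ran from -0.0377 to 0.11 for 4 injections, 0.0668 to 0.28 for 1 injection, -0.202 to 0.274 for wild-type and -0.242 to 0.255 for genotype. With the replicate block the counts were 1654 for 4 injections, 0 for 1 injection, 1 for genotype, 27 and 232 for the interactions and 2 for sex. Replicates 4, 5 and 6 occur only among wild-type controls, so that the block takes the 3 female wild-type controls out of every comparison. In each group of 3, replicate 1 is male and replicates 2 and 3 are female. The block therefore nearly coincides with sex, and its low counts for genotype, the interaction by genotype and sex cannot be read as instability alone.

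Among single genes, leaving out arrays kept 4412 values, weakened 580 below the threshold, raised 56 above it and moved 43. Among lists it kept 573, weakened 68 and reversed the camera direction, relative to the other genes, of 1. That direction reversed for cell cycle after 4 injections with the stricter filter (median 0.009, still positive), for matrix in the interaction by genotype with array weights (-0.055) and without MerCreMer 4 tamoxifen replicate 3 (-0.085, the lowest of a leave-one-out range up to 0.613), and, in the larger MerCreMer batch after 1 injection, for cytosolic chaperones (0.013) and erythroid markers (-0.232), and the cause was not tested. The median alone changed sign for fatty acid oxidation after 1 injection without MerCreMer 1 control replicate 3 (0.008), for immediate early genes after 1 injection in the larger MerCreMer batch (0.039), and for the sarcomere list in the interaction by genotype with array weights (0.057) and between genotypes with each array centred (0.023). The estimated correlation ended all 66 list calls, and fry kept 15. Of 120 named genes called after 4 injections, 98 were kept without replicate 3. In every setting that tested them, apart from the stricter thresholds, 6 were kept. Among these 6, Gpnmb did not pass the stricter filter on dim probe sets and was not tested there. Values below a log2 value of 5 were taken as near background. Genes that reached it on fewer than 3 arrays were not tested in the main setting, and changes there are not seen. A gene could pass through 1 group alone. Where a group compared lies below 5, as for Gpnmb, Ccl12 and Lcn2 in the MerCreMer 4 controls, the change is measured against background.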

Other observations

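The tests of cardiomyocyte share, Cre activity, a male mouse and a single X chromosome, the length limits other than 100 kb, and the comparison of long cardiomyocyte genes with long genes of other lists were chosen after the result was seen. Sex left a small signature in the ventricle across all groups, with 33 genes called by limma, 18 higher and 15 lower in males, 13 of them on the X or Y chromosome. The Y-linked genes Eif2s3y and Uty were higher in males by 5.29 and 4.31 log2 units. These differences are measured against background, with female arrays at 1.69 to 2.28 and 2.29 to 2.92. Genes that escape X inactivation were lower in males, with Eif2s3x at -0.61 (SE 0.0485), Kdm5c at -0.56 (SE 0.0498) and Kdm6a at -0.73 (SE 0.106). The following genes outside the sex chromosomes were chosen after their values were seen. C7, a complement component, was higher in males by 1.63 (SE 0.134, limma adjusted p = 9.21e-07), Hsd11b1, which regenerates active glucocorticoid, by 0.87 (SE 0.0958) and Scn4b, a sodium channel subunit, by 1.30 (SE 0.26). Lower in males were Col14a1 at -0.63 (SE 0.0958) and Lum, a small proteoglycan of the matrix, at -0.44 (SE 0.0836). The count was 21 without MerCreMer 1 control replicate 1 and 70 without MerCreMer 4 tamoxifen replicate 3, the array with low Xist.

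Both interactions also held immediate early genes and chaperones. The immediate early gene list had a median of 0.40 in the interaction by genotype (7 of 23 higher, 9 adjusted over the list alone, adjusted p = 0.00051, and adjusted p = 0.714 with an estimated correlation) and 0.47 in that by injection days (4 of 23 higher, 9 adjusted over the list alone, adjusted p = 0.000107, and adjusted p = 0.714 with an estimated correlation), which was 0.22 without MerCreMer 4 tamoxifen replicate 3. Cytosolic chaperones had medians of 0.22 in both (adjusted p = 0.00158 in each, and adjusted p = 0.585 with an estimated correlation), with Hsp90aa1 at 0.97 (SE 0.223) and 1.18 (SE 0.238).

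Long genes were lower after 4 tamoxifen injections in MerCreMer hearts, with 184 of 542 genes of at least 200 kb called lower and 16 higher, against 257 lower and 329 higher of 3006 under 10 kb. An array-wide loss of signal from long genes stays open at the size seen over all genes of at least 100 kb (median -0.073, and -0.059 without replicate 3). The 16 long members (at least 100 kb) of endothelial, fibroblast, smooth muscle and matrix lists had a median of 0.058 (-0.07 without replicate 3). Its 95% interval of -0.175 to 0.333 includes that size, so that the planned bound was met only within the spread. The 16 long cardiomyocyte, sarcomere and calcium genes had a median of -1.14 (-0.76 without replicate 3). They lay below the other 16 (permutation p = 1e-05, the smallest that 1e+05 resamples can give). An equal loss in all long genes therefore does not account for their fall. A lower share of cardiomyocyte RNA is argued against as the whole cause, because long cardiomyocyte genes lay -1.002 from the short ones (permutation p = 2e-05). These permutation tests treat genes on the same arrays as independent, which they are not. They also do not separate length from gene function. Cre activity in the nucleus cannot be told apart from other changes in these 3 hearts, since only that group combines Cre with repeated tamoxifen. The long-gene medians of its 3 arrays overlapped the 18 others at 100 kb (-0.128 to -0.035 against -0.04 to 0.053, exact two-sided permutation p = 0.00376; p = 0.000752 at 200 kb and 0.608 at 50 kb by the same test), which restates the fall and would follow from any cause of it.

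Xist was at 3.12 on MerCreMer 4 tamoxifen replicate 3, labelled female, against 7.38 to 8.03 on the other female arrays and 2.62 to 3.55 on male arrays. A male mouse is argued against, as none of the 3 Y-linked genes exceeded the highest other female array (largest gap -0.35). A single X chromosome could account for it but cannot be told apart from other causes, as 1 of 4 genes that escape X inactivation, Kdm6a at 5.69, lay at the male level of 5.67 to 6.3. Eif2s3x (9.31) and Kdm5c (7.78) lay between the sexes, above all male arrays (up to 9.12 and 7.53) and just below all other female arrays (from 9.42 and 7.8), and Ddx3x (9.58) lay in the female range (9.53 to 9.7). No biological explanation was tested beyond these.

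Other splits of the same arrays bear on the remaining counts. For 4 injections in MerCreMer mice the real split called 2653 genes and the highest other 1, for 1 injection 1 and 0, and for 4 against 1 control injections 0 and 0 by limma (375 with an unadjusted p under 0.05; all 10 splits alike), and in each the 10 splits are too few for a share under 0.05. For wild-type mice the real count was 0 in limma (294 with an unadjusted p under 0.05) and the highest other 3; as each of the 84 splits calls at least 0 genes, that count decides nothing. For genotype 1 of 84 splits, the real one, gave 77 genes and the highest other 1. Chance is argued against for that count, which does not separate genotype from other differences between the arrays of the 2 genotypes. For sex 1 of 100 gave 33 and the highest other 3. As 13 of the 33 lie on the X or Y chromosome, the real labels were bound to call more genes. That count therefore does not test the genes outside the sex chromosomes.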
